A study of Mus musculus with 12 samples.

How the data were processed

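The values are log2 expression per Affymetrix mouse probe set, used as deposited and produced with RMA per the submitters' processing notes, whose version is not given in the sources used here. The matrix holds 20523 probe sets in 12 columns, 3 for each of 4 groups of cultured aortic endothelial cells. The groups are wild type (WT), Ets1 null (Ets1KO), Ets2 null (Ets2KO) and null for both (labelled DKO). WT and Ets1KO cells carried an eGFP lentivirus and the other groups an eGFP and Cre lentivirus, so Cre cannot be separated from loss of Ets2. Sex is not given in the sources used here. The titles and genotypes call the Ets1KO and Ets2KO samples null while their short descriptions say wild type, and the titles and genotypes were followed.

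The third DKO column equals the mean of the first and second, to a tolerance of 1.00e-05, in 20521 of 20523 probe sets. It was left out of every test, so 11 arrays are analysed and DKO has 2. This departs from the plan, which had 12 arrays. The arrays labelled DKO also have lower values, with medians of 8.28 to 8.30 against 9.05 to 9.15 in the 9 others. For that reason comparisons with DKO are given both as deposited and relative to array medians (each array's median subtracted), and gene lists were tested relative to array medians. Both choices, and the splits of the WT arrays between comparisons, were made after the data were seen. The comparisons, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined.

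Probe sets were matched to genes with the platform annotation. Of 20523 probe sets, 18824 carry 1 symbol, 549 carry several and 1150 are unlisted. For each of 11015 genes the probe set with the highest mean was tested, and the others are quoted where they differ. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 group means, 7 residual degrees of freedom, 2.11 prior degrees of freedom). P-values were adjusted by Benjamini and Hochberg within each comparison, and a gene is called changed at adjusted p below 0.05. The interaction is the Ets2 loss effect in Ets1-null cells minus that in cells with Ets1. Values are group means with standard deviations across arrays. SE is the standard error of limma. The titles call the samples biological replicates, but nothing else says that they come from separate animals, so p-values may reflect technical spread.

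Gene lists (30, of which 29 had enough measured members, giving 174 tests) were tested with camera at its preset correlation of 0.01, with adjustment over all tests. They were tested again with the correlation between members estimated from the data, and with fry. The fit was tried on simulated data with errors drawn independently for each gene. In each comparison 100 genes were changed by a log2 of 1 and 100 by 3, up or down, in the same fit. At a log2 change of 1 it recovered 51% of them in Ets1KO, 43% in Ets2KO and 36% in DKO against WT, and at 3 it recovered 93%, 89% and 93%. False calls numbered 7, 7 and 8. Genes named in the text are the 10 largest rises and falls by log2 (5 for DKO against Ets2KO and the interaction) among called genes whose groups do not overlap, a condition not used for the interaction, and whose higher group lies above the median of all genes. Ets1, Ets2 and up to 4 called members of each list, or up to 2 others where none was called, are also named. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9, and all tests were run in R.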

Results

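Aortic endothelial cells from 4-week-old mice were cultured and profiled on Affymetrix arrays to ask what loss of the ETS transcription factors Ets1 and Ets2 does to endothelial gene expression. WT cells and Ets1KO cells with floxed Ets2 received a control eGFP lentivirus. Cells with floxed Ets2 received the Cre lentivirus in a background with Ets1 (Ets2KO) or without it (labelled DKO). Each group has 3 columns of values, and 11015 genes were tested.

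Before genes were compared, the columns were compared with each other. The third column labelled DKO is the mean of the first and second in all but 2 probe sets. The exceptions are Birc3, an inhibitor of apoptosis, and Sphk1, which makes sphingosine-1-phosphate. Birc3 reads 6.53 in the third column, where the mean of the first and second is 7.12, against 8.07 ± 0.63 in WT. Sphk1 reads 5.49, 5.73 and 5.71, where the mean is 5.61, against 7.08 ± 0.93 in WT. The tests therefore use 11 arrays, with 2 labelled DKO. Of these, 10 lie closest to an array of their own group by correlation, and WT replicate 3 lies closest to Ets1KO replicate 3 (r = 0.926). Medians are 8.28 to 8.30 in the arrays labelled DKO and 9.05 to 9.15 in the others. The median gene differs by -0.61 between DKO and WT, by 0.01 between Ets1KO and WT and by -0.02 between Ets2KO and WT.

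**Figure D1:**
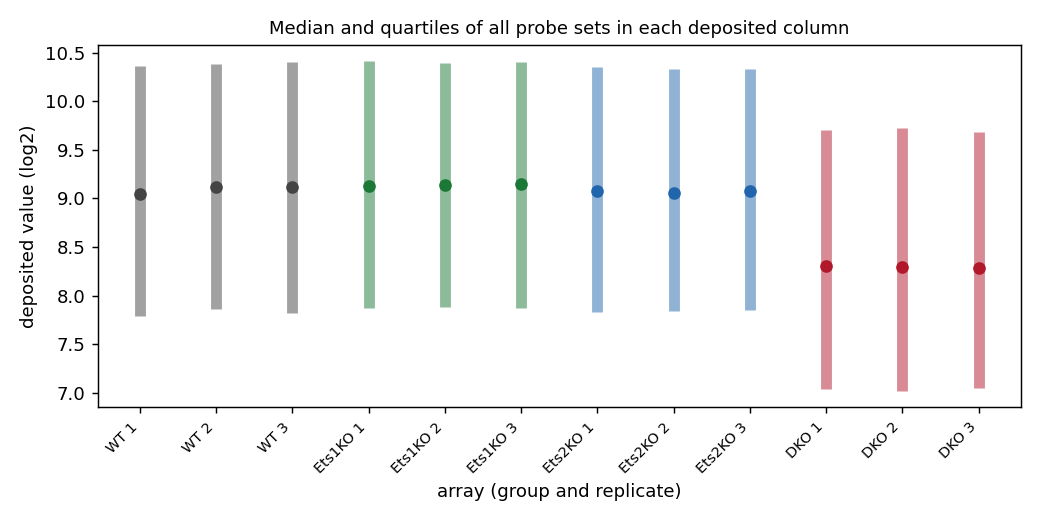
Median (point) and quartiles (bar) of log2 expression over all probe sets in each of the 12 columns, by group. The 3 columns labelled DKO have medians of 8.28 to 8.30 and the 9 others of 9.05 to 9.15.

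The transcripts of the targeted genes were read first. Ets1, which directs endothelial and angiogenic transcription, had 10.05 ± 0.21 in WT and 8.74 ± 0.43 in Ets1KO (n = 3 each). The difference was -1.31 (SE 0.23), and all 4 Ets1 probe sets were lower, with differences of -0.50, -0.70, -1.22 and -1.31. Among all genes the limma adjusted p was 0.203, and the exact permutation p was 0.1, the smallest that 3 against 3 arrays allow. In the arrays labelled DKO, which should lack Ets1 as well, Ets1 stood 2.16 above Ets1KO relative to array medians (SE 0.25, adjusted p = 0.000726) and 1.41 above it as deposited. The other 3 probe sets gave 1.95, 0.84 and -0.74. Against WT the brightest probe set was 0.81 higher relative to array medians (adjusted p = 0.0406) and 0.10 higher as deposited. The other 3 gave 0.70, 0.10 and -1.29 relative to array medians, the last lower at limma adjusted p = 0.00659 over all probe sets. Against Ets2KO the brightest probe set was 1.21 higher relative to array medians (adjusted p = 0.00808) and 0.51 higher as deposited. The other 3 gave 0.96, 0.73 and -0.76 relative to array medians. Ets2, the close relative of Ets1, was 9.70 ± 0.40 in Ets2KO and 10.14 ± 0.51 in WT, a difference of -0.44 (SE 0.38, adjusted p = 0.557, exact permutation p = 0.4), and its second probe set gave -0.18. In the arrays labelled DKO, Ets2 differed from Ets1KO by 0.68 relative to array medians and by -0.07 as deposited (adjusted p = 0.231 for the former). Against Ets2KO it was 1.32 higher relative to array medians (adjusted p = 0.0335) and 0.62 higher as deposited, and its second probe set gave 0.67 and -0.02. The arrays labelled DKO read 11.02 and 9.63 for Ets2, and the difference from Ets2KO is 0.65 without DKO replicate 1 and 1.99 without DKO replicate 2. The call is lost without DKO replicate 1, Ets1KO replicate 2, Ets2KO replicate 1 or Ets2KO replicate 2. Ets2 was 0.25 higher in Ets1KO than in WT (adjusted p = 0.877), and Ets1 differed by -0.41 in Ets2KO (adjusted p = 0.358). All 4 Ets1 probe sets were lower in Ets2KO (-0.54, -0.64, -0.27 and -0.41, exact permutation p = 0.1, 0.1, 0.3 and 0.2), so a smaller change is left open. Where the probe sets lie relative to the deleted exons is not given in the sources used here, so the level left in Ets1KO cannot be read as protein.

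**Figure D2:**
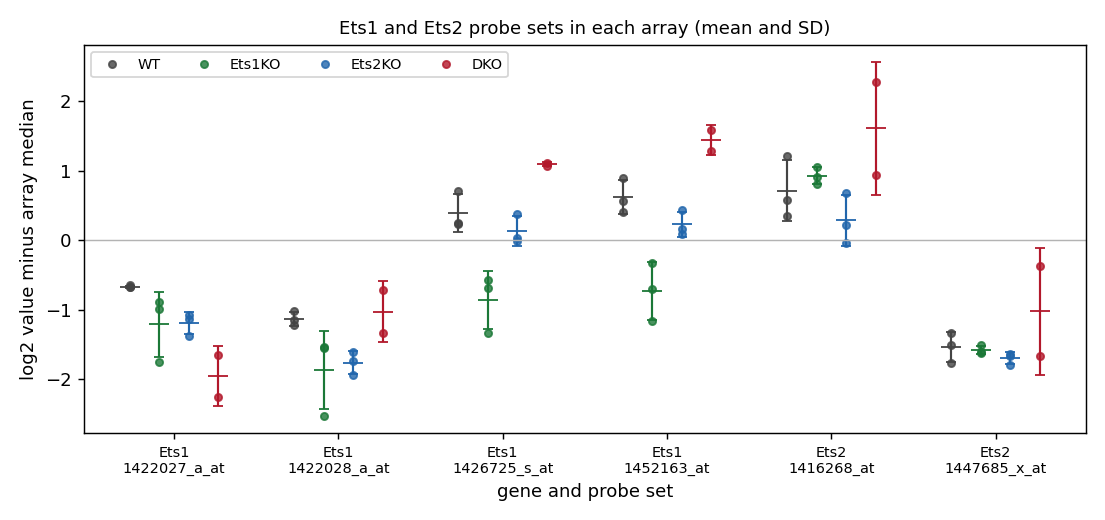
Log2 expression minus the array median (vertical axis) of 4 Ets1 and 2 Ets2 probe sets in each array (points), with group mean and SD (lines), for WT, Ets1KO, Ets2KO and DKO. The brightest Ets1 probe set reads 0.62 ± 0.24 in WT, -0.73 ± 0.42 in Ets1KO, 0.23 ± 0.18 in Ets2KO and 1.44 ± 0.21 in the 2 arrays labelled DKO.

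What Ets1 loss changes was asked by comparing Ets1KO with WT, both with the control virus. Ets2 alleles are floxed in Ets1KO and wild type in WT, so the alleles cannot be separated from Ets1 loss. By Xist and Eif2s3y all Ets1KO arrays are female-like while WT replicate 1 is male-like, so sex is not balanced either. Only Rnf130, a RING-type ubiquitin ligase, passed the test (log2 -3.58, SE 0.25, adjusted p = 0.00185). Its second probe set differed by -0.09, so the change rests on 1 probe set. Large differences that did not pass include the monocyte chemokines Ccl2 (-4.26, adjusted p = 0.501) and Ccl7 (-3.12, adjusted p = 0.519). The endothelial surface glycoprotein Cd34 (-3.25, adjusted p = 0.519), the TGF-beta co-receptor Eng (-1.22, adjusted p = 0.545) and the receptor Notch1 (-0.95, adjusted p = 0.236) also missed. Without 1 array at a time the comparison gave 1 to 15 genes and always kept Rnf130. With only the WT and Ets1KO arrays no gene passes (Rnf130 adjusted p = 0.0582, same difference), and 196 do with array weights. Among genes with a mean above the median, which leaves Rnf130 out, 0 pass by limma. It gave 9 without WT replicate 2, 15 without WT replicate 3, 12 without Ets1KO replicate 1, 2 without Ets1KO replicate 3, and 6 without DKO replicate 1 or without DKO replicate 2. At unadjusted p below 0.05 limma gives 954 genes, and 1972 genes (17.9%) have groups that do not overlap, where chance gives 10%.

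As sets, 2 lists were lower in Ets1KO. Inflammatory adhesion and chemokine genes had a median of -0.95, with 12 of 14 measured members (23 listed) below 0 (camera adjusted p = 0.0101, adjusted p = 0.997 with an estimated correlation). Interferon-stimulated genes had a median of -0.36, with 14 of 16 measured members (31 listed) below 0 (adjusted p = 0.0157, adjusted p = 0.997 with an estimated correlation). No member was called, with 0 of each list when adjusted over the list alone by limma, and the largest interferon differences were those of the guanylate-binding protein Gbp2 (-1.61, adjusted p = 0.652) and Rtp4 (-1.30, adjusted p = 0.545). The inflammatory call ends without WT replicate 1 (0.0738) or 2 (0.296), and the interferon call without WT replicate 1 (0.154), WT replicate 2 (0.296) or Ets1KO replicate 1 (0.0520). WT replicate 3 is the odd array here, with an inflammatory list mean of -1.06 relative to its median where the other WT arrays have 1.89 and 1.66. Endothelial identity genes, the class that ETS factors are known to activate, had a median of -0.47 with 8 of 9 measured members (28 listed) below 0 (camera adjusted p = 0.0579). By directional fry the adjusted p is 0.0856 relative to array medians. On deposited values, tried after the data were seen, it is 0.0205. Fibroblast markers (-0.42, adjusted p = 0.447) and basement membrane genes (-0.25, adjusted p = 0.310) did not pass.

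Ets2 loss together with Cre was asked about by comparing Ets2KO with WT, which gave 17 genes higher and 17 lower. The largest rises were in Apoe, a lipoprotein component (11.83 ± 0.99 against 7.02 ± 1.55, log2 4.80, SE 0.72, adjusted p = 0.0401), and in Itih5, a hyaluronan-binding matrix protein (10.72 ± 0.33 against 6.74 ± 1.41, 3.98, SE 0.59, adjusted p = 0.0401). Cysteine dioxygenase Cdo1 (2.40), the pterin dehydratase Pcbd1 (2.25), the acyl-CoA thioesterase Acot11 (2.20) and the Numb ubiquitin ligase Lnx1 (1.67, adjusted p = 0.0115) also rose. Smaller rises were those of the vitamin K reductase Vkorc1 (0.93), the ubiquitin adaptor Klhl26 (0.85) and Ppcdc of coenzyme A synthesis (0.74). The deepest fall was in Nfkbiz, a nuclear regulator of NF-kappa-B targets (8.70 ± 0.47 against 11.56 ± 0.54, -2.86, SE 0.34, adjusted p = 0.0272). Hypoxia-induced enzymes fell with it: Egln3, which marks HIF for destruction (-2.70, adjusted p = 0.0416), Pdk1, which keeps pyruvate from mitochondria (-2.02, adjusted p = 0.0459), and the collagen hydroxylase P4ha2 (-1.75, SE 0.23, adjusted p = 0.0272). Further falls were in the junction protein Ppl (-1.98, adjusted p = 0.0125), the small Maf factor Maff (-1.88), the immediate-early receptor Nr4a1 (-1.69), Avpi1 (-1.48) and Ifrd1 (-1.47). Ints6 fell by 1.84 at its brightest probe set, and another of its probe sets gave 0.55.

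The list of changed genes in Ets2KO is fragile. All Ets2KO arrays and WT replicate 1 are male-like by Xist and Eif2s3y, the other WT arrays female-like, and with sex as a covariate 4 genes are called, with 0 of the 34 kept. Only WT holds both sexes, so that fit sets Ets2KO against WT replicate 1 in effect. All 34 keep their direction in it, with a median absolute log2 of 1.50 (1.59 without the covariate), while the median SE goes from 0.20 to 0.29. These genes were called with WT replicate 1 among the WT arrays. For all 34 it lies nearer to the other WT arrays than to the Ets2KO mean. The kept direction was therefore nearly given by the choice of genes and does not test sex. Leaving out an array gave 0 to 69 genes: 0 without Ets2KO replicate 1, 8 without Ets2KO replicate 2, 7 without Ets2KO replicate 3, 9 without WT replicate 2 and 69 without WT replicate 3. It gave 5 without Ets1KO replicate 2, 4 without Ets1KO replicate 3 and 17 without DKO replicate 1 or without DKO replicate 2, arrays that enter only through the variance. All 19 named genes, Apoe and Nfkbiz among them, are lost without Ets2KO replicate 1, and Apoe, Acot11, Vkorc1, Egln3 and Pdk1 without WT replicate 3. Lnx1 and Ppl are kept in the 10 other fits that leave out an array. At unadjusted p below 0.05 limma gives 2088 genes, and 2918 (26.5%) have groups that do not overlap, where chance gives 10%. Among larger differences that did not pass are the endothelial tip marker Esm1 (-7.00, adjusted p = 0.176), the pericyte regulator Rgs5 (4.94, adjusted p = 0.131), cyclooxygenase Ptgs2 (-3.93, adjusted p = 0.0631) and the contractile actin Acta2 (-2.67, adjusted p = 0.177).

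Hypoxia and glycolysis, cholesterol synthesis and immediate-early genes were lower in Ets2KO as sets by camera, though not with an estimated correlation. All 17 measured hypoxia and glycolysis genes (18 listed) were below 0, with a median of -1.10 (camera adjusted p = 2.38e-11, adjusted p = 0.997 with an estimated correlation). Egln3, Pdk1 and P4ha2 were called, and 14 were when adjusted over the list alone. All 15 measured cholesterol synthesis genes (19 listed) were below 0, with a median of -1.65 (adjusted p = 1.21e-08, adjusted p = 0.997 with an estimated correlation). The cholesterol carrier Stard4 was called (-1.95, SE 0.31, adjusted p = 0.0481), and 9 genes were when adjusted over the list alone. Immediate-early genes had a median of -0.94 with 14 of 15 below 0 (adjusted p = 1.63e-04, adjusted p = 0.997 with an estimated correlation), with Nr4a1 called and 4 when adjusted over the list alone. By directional fry relative to array medians, hypoxia and glycolysis keeps an adjusted p of 0.0123, and cholesterol synthesis and immediate-early genes have 0.0856 each. On deposited values, tried after the data were seen, fry gives 0.00493, 0.0328 and 0.0191 in that order.

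Further list calls in Ets2KO rest on few arrays. Cell cycle genes had a median of -1.47 with all 28 measured members below 0 (adjusted p = 3.39e-05, adjusted p = 0.997 with an estimated correlation). The replication factors Cdc6 (-2.43, adjusted p = 0.151) and Mcm5 (-2.18, adjusted p = 0.223) were not called alone, and 0 were when adjusted over the list alone by limma. The cell cycle call ends without Ets2KO replicate 3 (0.111), since the Ets2KO arrays average 1.70, 1.54 and -2.04. In array order, marker lists of other cell types average -0.60, 0.89 and 2.08 for adipocytes, 0.13, -0.72 and 1.17 for pericytes and 0.29, 0.83 and 1.25 for fibroblasts, highest in the third array. Smooth muscle (-1.24, -1.78 and -1.45) and macrophage and leukocyte markers (-2.14, -1.73 and -2.35) are not. Genes induced by p53 had a median of 0.73 with 19 of 20 above 0 (adjusted p = 0.0111, adjusted p = 0.997 with an estimated correlation). The p53-induced Pmaip1 (2.19, adjusted p = 0.246) and Trp53inp1 (1.91, adjusted p = 0.233) led it without passing, and 0 were called when adjusted over the list alone by limma. That call ends without WT replicate 3 (0.462), as the WT arrays average 0.64, 1.03 and -0.93. Inflammatory genes had a median of -1.13 with 11 of 14 below 0 (adjusted p = 0.0130, adjusted p = 0.997 with an estimated correlation), with 6 called when adjusted over the list alone. Without WT replicate 1 (0.0932) or WT replicate 2 (0.157) that call ends. Ccl2 differed by -4.07 (adjusted p = 0.175), with an SD of 3.10 among the WT arrays that both single losses are compared with.

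**Figure D3:**
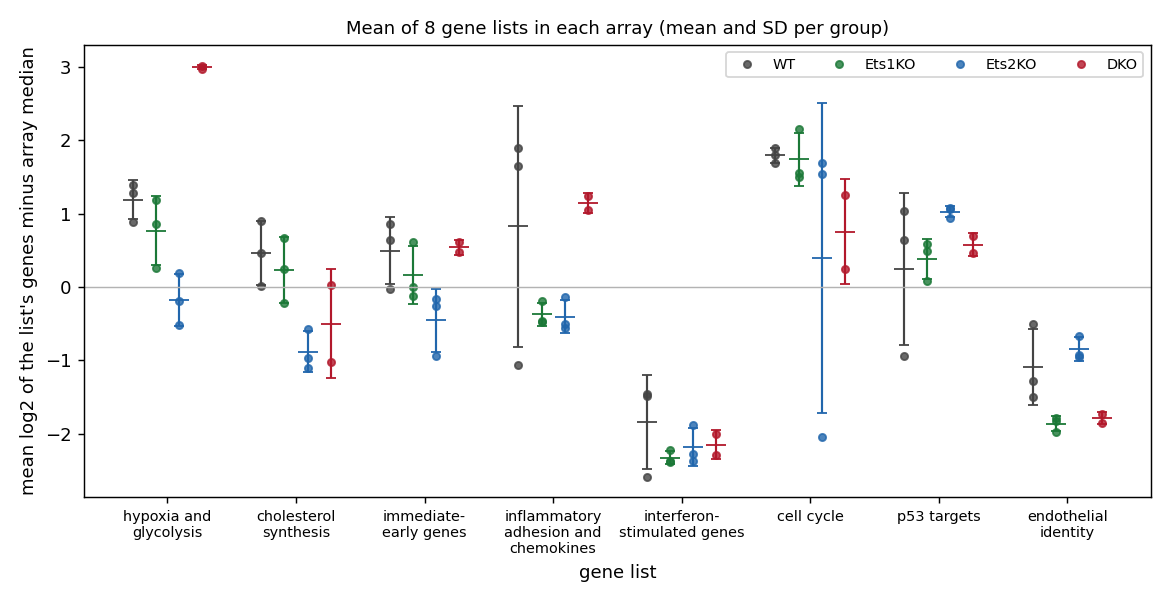
Mean log2 expression of the measured members of 8 gene lists minus the array median (vertical axis) in each array (points), with group mean and SD (lines), for WT, Ets1KO, Ets2KO and DKO. Hypoxia and glycolysis genes average 1.19 ± 0.26 in WT, 0.77 ± 0.47 in Ets1KO, -0.17 ± 0.35 in Ets2KO and 3.0 ± 0.03 in the 2 arrays labelled DKO.

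Loss of both factors was asked about by comparing the arrays labelled DKO with WT. As deposited 258 genes are higher and 4764 lower (5.14% higher), and relative to array medians 1779 are higher and 1312 lower (57.6% higher). With quantile normalization 1348 are higher and 1439 lower (48.4% higher). With the mean of a gene's probe sets, relative to array medians, 1443 are higher and 1487 lower (49.2% higher). The balance of rises and falls thus depends on the processing. Relative to array medians, groups do not overlap for 5750 genes (52.2%), where chance gives 20%. Gene values from here on are relative to array medians. The shift of the DKO arrays is not the same at all levels. Against WT, sorted values differ by -0.38 at the 99th percentile, while subtracting medians adds 0.71. Rises of the brightest genes may therefore be enlarged by the subtraction. The largest rises include Ppp1r3c, which targets a phosphatase to glycogen (4.54, SE 0.97, adjusted p = 0.00887, though its other probe set gave -0.50), the collagen cross-linker Lox (3.98, SE 1.31, adjusted p = 0.0489) and glycolytic Aldoc (3.80, SE 0.50, adjusted p = 0.00137). Others are hypoxia-induced Ankrd37 (3.80, adjusted p = 0.00415), the vascular transcription factor Mef2c (3.64, adjusted p = 0.00525), the matrix proteoglycan Prelp (3.64) and the lipoprotein receptor Vldlr (3.52). Proser2 (4.16), Fhl1 (3.66) and Kbtbd11 (3.59) rose as far. The deepest falls were in the pentraxin Nptx1 (-4.93, SE 1.46, adjusted p = 0.0334), the anaphase-promoting complex subunit Anapc5 (-4.17, SE 0.27, adjusted p = 1.34e-04) and the G protein subunit Gna12 (-3.72, SE 0.36, adjusted p = 3.25e-04). The centromere protein Cenpb (-3.53), the survival factor Bcl2l1 (-3.31, SE 0.45, adjusted p = 0.00157), the nucleoside transporter Slc29a1 (-3.39) and the sialyltransferase St3gal4 (-3.18) also fell. Grb10 (-3.82), Mbnl3 (-3.55) and Tmem120a (-3.51) complete the largest falls. Other ETS genes fell too, the repressor Erf by 1.85 (adjusted p = 3.68e-04), Etv4 by 1.75 and Etv5 by 1.36, while Etv3 rose by 0.73 only relative to array medians (0.02 as deposited), and that list as a set had adjusted p = 0.107.

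How far these changes can be read as expression is limited by the probe sets. Between Ets1KO and WT the probe sets of 1 gene have an intraclass correlation of 0.767, and between Ets2KO and WT 0.728, over 4785 genes with several. It is 0.289 for the arrays labelled DKO against WT, 0.270 against Ets1KO and 0.407 against Ets2KO. Genes with probe sets beyond 1 in both directions number 0 in Ets1KO and 2 in Ets2KO against WT, but 148 in DKO against WT. Actb, a common reference transcript, shows it: 1 of its probe sets goes from 2.67 ± 0.76 in WT to 4.54 ± 0.06 in DKO and another from 4.92 ± 0.48 to 4.20 ± 0.24. Without DKO replicate 2 the count against WT is 1905 relative to array medians, and 8 named genes are lost: Ppp1r3c, Proser2, Lox, Fhl1, Vldlr, Nptx1, Grb10 and Mbnl3. Over all 11 such fits Lox loses its call in 9, Fhl1 in 8, Nptx1 and Mbnl3 in 4 each, Grb10 in 3 and Vldlr in 2. Anapc5, Gna12, Cenpb, Bcl2l1, Aldoc and Ankrd37 are kept whichever array is left out, which cannot test a distortion shared by the arrays labelled DKO.

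Among lists, hypoxia and glycolysis genes rose against WT, with a median of 1.70 and all 17 above 0 (camera adjusted p = 3.39e-05, adjusted p = 0.997 with an estimated correlation). P4ha2 (3.33, SE 0.25, adjusted p = 1.45e-04), Egln3 (3.22) and the stress-responsive Ndrg1 (3.17) are among 11 members called, and 11 were when adjusted over the list alone. Cholesterol synthesis genes fell, with a median of -0.90 and 13 of 15 below 0 (adjusted p = 0.0127, adjusted p = 0.997 with an estimated correlation). The farnesyl diphosphate synthase Fdps (-2.74, SE 0.55, adjusted p = 0.00676), the sterol sensor partner Insig1 (-1.90), Dhcr7 (-1.73) and Mvk (-1.01) were called, with 4 when adjusted over the list alone. That call ends without WT replicate 2 (0.0822) or DKO replicate 2 (0.373). Cell cycle genes had a median of -0.85 with 27 of 28 below 0 (adjusted p = 0.0424, adjusted p = 0.997 with an estimated correlation), and 1 was called when adjusted over the list alone. Its called member E2f1, which drives entry to S phase (-1.41, adjusted p = 0.0118), has a second probe set at 0.01. That call ends without WT replicate 1 (0.0563), WT replicate 2 (0.0564), WT replicate 3 (0.0946), Ets1KO replicate 1 (0.0519) or DKO replicate 2 (0.373). Tested as deposited by camera, which sets a list against all other genes, cholesterol synthesis has 0.206. Cell cycle turns relative to the other genes and loses its call (adjusted p = 0.979). Its members stay lower as deposited, with a median of -1.56.

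To ask what Ets2 loss adds without Ets1, the arrays labelled DKO were compared with Ets1KO. As deposited 191 genes are higher and 4677 lower (3.92% higher), and relative to array medians 1899 and 1244 (60.4% higher), with groups apart for 6397 genes (58.1%, chance 20%). The share higher is 46.3% with quantile normalization and 50.7% with the mean of probe sets relative to array medians. The iron-binding acute-phase protein Lcn2 rose most (6.24, SE 1.74, adjusted p = 0.0269), with Vldlr (4.85, SE 0.94, adjusted p = 0.00633), Tmem45a (4.76), the cytokine Lif (4.40, SE 1.37, adjusted p = 0.0397) and glycogen phosphorylase Pygl (4.31, adjusted p = 0.0420). Ppp1r3c (4.25, other probe set -0.90), carbonic anhydrase Car9 (4.06, adjusted p = 0.00579), Aldoc (3.99), Kbtbd11 (3.83) and the vasodilator peptide Adm (3.83, adjusted p = 0.0174) follow. Falls were in Anapc5 (-4.23, SE 0.27, adjusted p = 9.28e-05), Cenpb (-4.12), cathepsin Ctse (-3.93), Slc29a1 (-3.76) and Bcl2l1 (-3.74, SE 0.45, adjusted p = 8.58e-04). Tmem120a (-3.55), Gna12 (-3.54), the sulfhydryl oxidase Qsox1 (-3.27), Wfdc3 (-3.23) and St3gal4 (-3.21) also fell. Leaving out an array gives 1982 to 3496 genes relative to array medians, with 2092 without Ets1KO replicate 2 and 1982 without Ets1KO replicate 3. Of 11 such fits, Pygl loses its call in 8, Lif in 7, Lcn2 in 4, and Adm and Ppp1r3c in 1 each.

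Hypoxia and glycolysis genes had a median of 2.25 against Ets1KO with all 17 above 0 (adjusted p = 1.14e-06, adjusted p = 0.997 with an estimated correlation). The list had 16 members called, led by Car9, Adm, Ndrg1 (3.80) and P4ha2 (3.47, adjusted p = 1.15e-04), and 16 when adjusted over the list alone. Cell cycle genes had a median of -0.87 (adjusted p = 0.0281, adjusted p = 0.997 with an estimated correlation), lost without Ets1KO replicate 3 (0.107) or DKO replicate 2 (0.340), with E2f1 (-1.50) the 1 member called when adjusted over the list alone. Cholesterol synthesis genes had a median of -0.72 (adjusted p = 0.0410, adjusted p = 0.997 with an estimated correlation), with Fdps (-2.73), Insig1 (-1.92) and Dhcr7 (-1.20) called and 2 when adjusted over the list alone. That call is lost without Ets1KO replicate 1 (0.0561), Ets1KO replicate 2 (0.135) or DKO replicate 2 (0.696). Of inflammatory genes, Ptgs2 (3.79, adjusted p = 0.0113), the NF-kappa-B inhibitors Tnfaip3 (2.47, other probe set -0.62) and Nfkbia (1.70), and the chemokine Ccl5 (2.46) rose, while the list had adjusted p = 0.319.

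What Ets1 loss adds in cells with Cre was asked by comparing the arrays labelled DKO with Ets2KO. As deposited 333 genes are higher and 4742 lower (6.56% higher), and relative to array medians 1861 and 1454 (56.1% higher), with groups apart for 6079 genes (55.2%, chance 20%). The share higher is 46.8% with quantile normalization and 48.0% with the mean of probe sets relative to array medians. Ptgs2 rose most (6.79, SE 0.85, adjusted p = 8.23e-04), followed by Xist, the RNA that silences an X chromosome (6.36), Lox (5.94), Egln3 (5.91, SE 0.45, adjusted p = 1.02e-04) and pantetheinase Vnn1 (5.81). Apoe (-6.47, SE 0.81, adjusted p = 8.51e-04), Nptx1 (-5.70), the Y-linked Eif2s3y (-5.29), Itih5 (-5.12, SE 0.64, adjusted p = 8.23e-04) and the lipase Pla2g7 (-4.72) fell. Xist and Eif2s3y mark sex rather than Ets loss, and this comparison sets female-like arrays against male-like ones for every gene. With sex as a covariate, which rests on WT replicate 1 alone, 262 genes pass relative to array medians instead of 3315, and 249 of the 3315 are kept. Of the 3315, 3310 keep their direction in that fit, while the median SE goes from 0.21 to 0.35. These genes were called with a spread that includes that of the WT arrays. Their kept direction was therefore largely given by the choice of genes and does not test sex. Eif2s3y reads 9.30 to 10.23 in all Ets2KO arrays and 9.37 in WT replicate 1, and 3.12 to 3.66 in every other array. Of 11 fits that leave out an array, Eif2s3y loses its call in 5, Nptx1 in 4 and Lox in 1. Hypoxia and glycolysis genes had a median of 2.68 with all 17 above 0 (adjusted p = 5.07e-10, adjusted p = 0.997 with an estimated correlation). Ankrd37 (5.63), hexokinase Hk2 (5.50) and P4ha2 (5.06, adjusted p = 3.40e-05) are among 16 called, and 17 were when adjusted over the list alone. Endothelial genes Plvap (-2.49, adjusted p = 0.0271) and Eng (-2.27, adjusted p = 0.0186) fell, Notch1 fell by 2.29 (adjusted p = 1.73e-04), and Acta2 (3.70, adjusted p = 0.0240) and Col1a1 (3.42, adjusted p = 0.00379) rose. The lists that hold them have no call by camera (adjusted p = 0.187 for endothelial identity, 0.940 for Notch, 0.840 for smooth muscle and 0.950 for fibroblast markers), while mixed fry, which takes both directions, calls the first (0.00431), the second (4.03e-07) and the last (1.09e-04). Fry does not set a list against other genes, and 30.1% of all genes are called here. Its calls therefore cannot show that these lists differ from the rest.

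Whether Ets2 loss acts alike with and without Ets1 was asked by setting Ets2KO minus WT beside DKO minus Ets1KO, which share no array. Across genes the differences correlate at r = 0.08 (Spearman rho 0.13), with r of -0.04 to 0.14 when an array is left out. Simulated unrelated differences gave r up to 0.05. That simulation drew each gene independently, while genes here vary together (estimated correlation 0.88 among cell cycle genes). It therefore cannot tell whether 0.08 lies beyond chance. Of 17 genes higher in Ets2KO, 4 are also called higher against Ets1KO, where 2.93 are expected by chance (Fisher p = 0.517). Of 17 lower genes, 3 are also called lower (1.92 expected, Fisher p = 0.430) and 6 are called the other way, the hypoxia gene P4ha2 among them. Of the 17 higher genes, 1 is called the other way. Calls in the other direction were not tested. Among all 11015 genes, 1899 are called higher against Ets1KO relative to array medians, and 191 as deposited. Setting Ets1KO minus WT beside DKO minus Ets2KO gave r = 0.20 (0.06 to 0.31 with an array left out), and Rnf130 is called in both (0.132 expected, Fisher p = 0.132). Both comparisons set female-like arrays against a group that holds male-like ones. A shared sex difference could therefore add to this r, which was not tested. Comparisons that share the WT arrays have a correlation built in. Ets1KO and Ets2KO against WT have r = 0.12 where a simulation with no true effect gives 0.50 (covariance 0.0355 against 0.0788), and Ets1KO and DKO against WT have 0.32 where it gives 0.45 (covariance 0.130 against 0.0797). With 1 WT array given to one comparison and the other WT arrays to the other, the 6 splits give r of -0.27 to 0.10 for the former pair and -0.03 to 0.18 for the latter. Genes lying near the deleted genes were also counted, though with so few calls this test has little power. Of the 20 nearest genes measured, 0 were called by limma around Ets1 in Ets1KO (2 at unadjusted p below 0.05, Fisher p = 0.690) and 0 around Ets2 in Ets2KO (5 at unadjusted p below 0.05, Fisher p = 0.565).

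**Figure D4:**
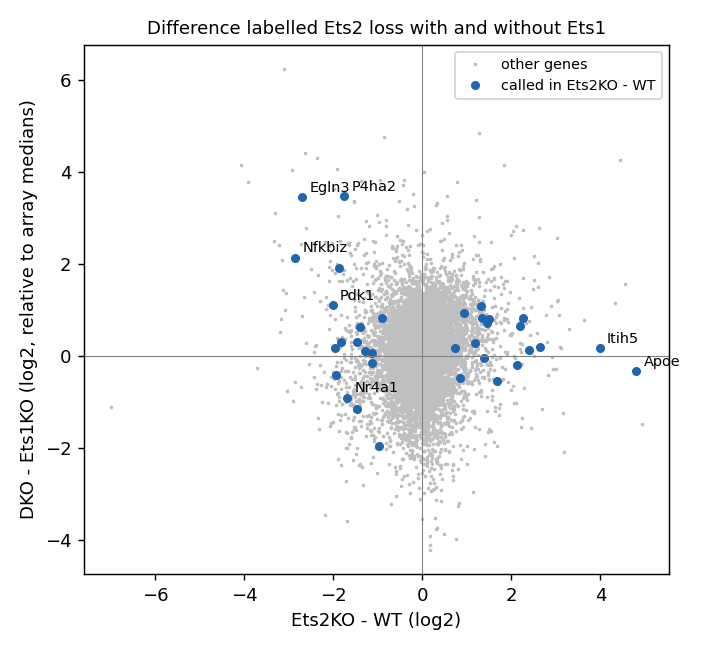
Each point is 1 of 11015 genes, with log2 Ets2KO minus WT on the horizontal axis and log2 DKO minus Ets1KO, relative to array medians, on the vertical axis. Blue points are the 34 genes called in Ets2KO against WT, with hypoxia gene P4ha2 at -1.75 and 3.47, and the correlation over all genes is 0.08.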

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

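The tests of technical explanations and of probe sets without a single gene symbol, and the use of values relative to array medians, were chosen after the results were seen, while the interaction was planned.

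The interaction, the test of whether Ets2 loss acts differently without Ets1, is set off here because the groups differ under the same contrast. Relative to array medians 1562 genes pass (800 higher, 762 lower, 51.2% higher), and as deposited 3438 do (165 higher, 3273 lower, 4.80% higher). With quantile normalization 1290 do (466 higher, 824 lower, 36.1% higher). Of the 1562, 1357 are also among the 3143 called in DKO against Ets1KO, and 23 among the 34 called in Ets2KO against WT. Both comparisons are terms of the interaction and differ in length, so these overlaps cannot show which of them drives it. The highest values are those of acute-phase Lcn2 (9.35, SE 2.33, adjusted p = 0.0302), the chemokine Ccl2 (8.20, adjusted p = 0.0328), cyclooxygenase Ptgs2 (7.71, SE 1.14, adjusted p = 0.00413), the cytokine Lif (7.02) and glycogen phosphorylase Pygl (6.66). The lowest are those of the lipase Pla2g7 (-5.28), the lipid carrier Apoe (-5.16, adjusted p = 0.0166), Anapc5 (-4.42, adjusted p = 6.21e-04), the death-associated kinase Dapk3 (-4.38, adjusted p = 2.82e-04) and Cenpb (-4.30). Ets1 itself has 2.56 at its brightest probe set (SE 0.34, adjusted p = 0.00259), and its other probe sets give 2.21, 1.47 and -0.22. Of 11 fits that leave out an array, Ccl2 and Lif lose their call in 9 each, Pygl in 8, Lcn2 in 7, and Pla2g7 and Apoe in 1 each (without DKO replicate 1). Ptgs2, Anapc5, Dapk3 and Cenpb keep theirs in all. Leaving out an array cannot test a distortion shared by the arrays labelled DKO, which enter every interaction value. Probe sets of 1 gene have an intraclass correlation of 0.270 in DKO against Ets1KO, and 0.767 in Ets1KO against WT. Whether these values reflect expression is therefore open. With sex as a covariate 595 genes pass. The count is 936 without Ets1KO replicate 2, 910 without Ets1KO replicate 3, 991 without Ets2KO replicate 1, 1000 without Ets2KO replicate 2 and 1022 without DKO replicate 1.

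Lists set off by the same test are hypoxia and glycolysis, with a median of 3.33 (all 17 above 0, 16 called, 17 when adjusted over the list alone, camera adjusted p = 1.57e-11, adjusted p = 0.997 with an estimated correlation), and inflammatory genes, with a median of 2.00. The latter have 11 of 14 above 0 and 6 called, also 6 when adjusted over the list alone (adjusted p = 0.0424, adjusted p = 0.997 with an estimated correlation). Egln3 (6.13, adjusted p = 7.94e-04), Car9 (5.95), Hk2 (5.38) and P4ha2 (5.21) lead the first, and Ccl2, Ptgs2, the chemokine Ccl7 (6.39) and Tnfaip3 (4.64) the second. The inflammatory call is lost without WT replicate 1 (0.0738) or 2 (0.121), Ets1KO replicate 1 (0.0563) or 2 (0.0510), Ets2KO replicate 1 (0.0537) or 3 (0.0507), and DKO replicate 1 (0.0779) or 2 (0.101).

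Probe sets without a single gene symbol (1699) lie outside the gene tests and were tested apart. Of these 10 pass in Ets2KO against WT (7 higher, 3 lower) and 638 in the arrays labelled DKO against WT (421 higher, 217 lower).

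The first pattern weighed is the large number of genes that differ between the arrays labelled DKO and WT. An offset added to those columns is argued against as the whole cause, since 3091 genes still pass once each array's median is subtracted. A technical difference acting on single probe sets could account for many of them, since probe sets of 1 gene have an intraclass correlation of 0.289 here and 0.767 between Ets1KO and WT. Loss of both factors stays open. Of called genes with several probe sets, 30.1% have other probe sets on the opposite side of 0, which leaves room for both, and the arrays labelled DKO cannot be separated from their processing.

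The second pattern is lower hypoxia and glycolysis genes in Ets2KO than in WT. Sex could contribute, since Xist and Eif2s3y mark all Ets2KO arrays as male-like. The single male-like WT array has a list mean of 0.891, above the highest Ets2KO array (0.190), but 1 array decides nothing. The Cre virus and loss of Ets2 cannot be told apart, as only floxed cells given Cre are labelled Ets2KO, and Ets2 signal itself is not clearly lower in them (-0.44, adjusted p = 0.557). The arrays labelled DKO also had Cre and have a list median of 2.25 above Ets1KO, the other direction, but whether those values reflect expression is itself open.

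The third pattern is that Ets1 is not lower in the arrays labelled DKO than in Ets1KO. An exchange of the DKO and WT labels is argued against, since Ets1KO lies 1.31 below the arrays labelled WT (Ets1KO minus WT -1.31). A technical difference acting on single probe sets could be the cause, since the 4 Ets1 probe sets of DKO minus Ets1KO span 2.91, against 0.81 in Ets1KO minus WT. A persisting transcript alone would read alike in Ets1KO, which has the same Ets1 genotype, and so leaves the excess of DKO over Ets1KO (2.16, SE 0.25, and 1.41 as deposited) unaccounted for. A change in the level of such a transcript on Ets2 loss stays open and was not tested.

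Splitting the same 6 arrays into other groups of 3 gives only 10 splits, too few for a share under 0.05. For Ets1KO and WT the real split gives 1 gene and the highest other 1, so 2 of 10 splits reach the real count. For Ets2KO and WT the real split gives 34 and the highest other 2, so 1 of 10 splits, the real one, reaches it.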

How the results depend on the processing

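The use of values relative to array medians, of all 12 columns, of deposited values in camera and of sex as a covariate was chosen after the data were seen, and the other alternatives before. Of 240 tests of named genes under an alternative, 203 kept direction and side of the threshold, 37 lost the call and 0 reversed. With 1 array left out, 640 of 880 kept the call and 240 lost it. Of 118 tests of list calls 65 kept the call, 51 lost it and 2 reversed, and with 1 array left out 158 of 187 kept it. The 2 are cell cycle in DKO with deposited values in camera, where only the direction relative to other genes turned. Where an array labelled DKO is left out, the other is assumed to vary like the rest. The cause of the changes below was not tested.

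Replicate numbers were not taken to pair the samples. Of 15 pairs with the same number 1 has a correlation over 0.1 (range -0.32 to 0.10). Between WT and Ets1KO, however, same-number pairs have 0.09, 0.07 and 0.10 and the others -0.09 to -0.01, so pairing there stays open. Deviations of 2 DKO arrays from their mean mirror each other, so pairs with DKO decide nothing. With a replicate block 5 genes are called in Ets2KO and 972 in the interaction relative to array medians, and the adjusted p is 0.0515 for cholesterol synthesis in DKO against Ets1KO and 0.0835 for inflammatory genes in the interaction. The block changed no other count by over 1.5 times.

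As deposited, Ets1KO against WT gave 196 genes with array weights, 0 among genes above the median, 0 with only the arrays of both groups and 7 with all 12 columns. Ets2KO against WT gave 1044 with array weights, 52 with the mean of probe sets, 101 over all probe sets, 0 at adjusted p under 0.01, 0 with only the arrays of both groups, 285 with all 12 columns and 4 with sex as a covariate, none of them among the 34. DKO against WT, Ets1KO and Ets2KO and the interaction gave 2787, 2590, 2961 and 1290 with quantile normalization, and 3091, 3143, 3315 and 1562 with each median subtracted. They gave 2480, 2496, 2439 and 1746 among genes above the median, and 3228, 3171, 3314 and 1770 at adjusted p under 0.01. At 2-fold or more DKO gave 2804, 2763 and 2949. Over all probe sets the interaction gave 5577, and DKO against Ets2KO gave 2159 with sex as a covariate.

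Relative to array medians, DKO against WT, Ets1KO and Ets2KO and the interaction gave 1768, 1824, 1876 and 983 among genes above the median, 5368, 5215, 5341 and 3087 over all probe sets, and 1424, 1339, 1529 and 455 at adjusted p under 0.01. At 2-fold or more DKO gave 1499, 1412 and 1669. With only the arrays of both groups DKO gave 1324 against WT and 1880 against Ets2KO. The interaction gave 2593 with all 12 columns. With sex as a covariate DKO against Ets2KO gave 262 and the interaction 595.

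Leaving out 1 array gave 1 to 15 genes in Ets1KO, 0 to 69 in Ets2KO, and for DKO against WT, Ets1KO and Ets2KO 3885 to 5505, 3892 to 5258 and 4010 to 5390 as deposited. Relative to array medians it gave 1905 to 3414, 1982 to 3496 and 2251 to 3639. The interaction gave 2614 to 3740 and 910 to 1659, and list calls numbered 12 to 23. The correlation of both Ets2 loss effects was -0.0395 to 0.14 and of both Ets1 loss effects 0.0618 to 0.31, and the latter was 0.11 among genes above the median.

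Of 17 list calls, 0 were left with an estimated correlation (each at adjusted p 0.997), 8 among genes above the median, and fry in its mixed form gave 58. Directional fry gave, in Ets1KO, 0.446 for interferon and 0.464 for inflammatory genes. In Ets2KO it gave 0.470 for cell cycle, 0.468 for p53, 0.446 for inflammatory, 0.0856 for immediate-early and 0.0856 for cholesterol genes. In DKO it gave 0.688 and 0.713 for cell cycle and 0.331 and 0.464 for cholesterol (against WT and Ets1KO), and 0.193 for inflammatory genes in the interaction. On deposited values, where the DKO arrays have lower medians, it gave 0.208 and 0.208 for cell cycle and 0.0221 and 0.0328 for cholesterol. In Ets2KO deposited values gave 0.0191 for immediate-early and 0.0328 for cholesterol genes. Mixed fry gave 0.144 for interferon and 0.132 for inflammatory genes in Ets1KO, and 0.273 for cell cycle, 0.409 for p53 and 0.0503 for inflammatory genes in Ets2KO. In DKO it gave 0.436 and 0.436 for cell cycle and 0.0534 and 0.106 for cholesterol. Among genes above the median, inflammatory genes had 0.396 in Ets1KO, 0.858 in Ets2KO and 0.858 in the interaction, and p53 targets had 0.0606. Cell cycle had 0.0997 and 0.0797 and cholesterol 0.350 and 0.420 in DKO. With deposited values in camera, cholesterol had 0.206 and 0.347. Cell cycle reversed relative to the other genes (0.979 and 0.965), while its members stayed lower (medians -1.56 and -1.63). With all 12 columns inflammatory genes in the interaction had 0.0524.

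With 1 array left out, adjusted p was 1.43e-07 to 0.296 for interferon and 5.44e-09 to 0.296 for inflammatory genes in Ets1KO. In Ets2KO it was 9.29e-09 to 0.111 for cell cycle, 9.76e-06 to 0.462 for p53, 2.91e-08 to 0.157 for inflammatory, 1.65e-06 to 0.0150 for immediate-early, 1.64e-14 to 1.68e-08 for hypoxia and 1.37e-10 to 2.47e-06 for cholesterol genes. In DKO against WT it was 2.46e-05 to 0.373 for cell cycle, 6.57e-06 to 3.51e-04 for hypoxia and 9.77e-05 to 0.373 for cholesterol. Against Ets1KO it was 1.68e-05 to 0.340, 2.83e-08 to 1.35e-05 and 1.44e-04 to 0.696. Against Ets2KO hypoxia had 8.23e-11 to 7.99e-09, and in the interaction inflammatory genes had 6.17e-05 to 0.121 and hypoxia 2.81e-13 to 8.42e-10.

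Ets1 had 0.0812 in DKO against WT and 0.53 against Ets2KO with the mean of probe sets, and 0.68 against WT with quantile normalization. A single Ets1 probe set reversed the direction in DKO against WT, Ets1KO and Ets2KO and in the interaction (-1.29, -0.74, -0.76 and -0.22), another gave 0.10, 0.84 and 0.73, and a further one 0.70 against WT. Ets2 in DKO against Ets2KO had 1.0 with the mean of probe sets, 1.18 with quantile normalization and 0.67 with its second probe set, which gave -0.00349 in Ets1KO. With 1 array left out Ets1 spanned -1.52 to -1.09, -0.53 to -0.31, 0.66 to 0.97, 1.95 to 2.37, 1.06 to 1.36 and 2.34 to 2.76, and Ets2 0.04 to 0.53, -0.66 to -0.16, 0.22 to 1.57, 0.00779 to 1.35, 0.65 to 1.99 and 0.44 to 1.78, in Ets1KO, Ets2KO and DKO against WT, DKO against Ets1KO and Ets2KO, and the interaction.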

Other observations

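The list tests in this part were planned, and centring on array medians, fry on deposited values and the sex tests were chosen after the data were seen. In the arrays labelled DKO single members of further lists passed, while camera called none of these lists against WT. Of all genes 28.1% are called in that comparison relative to array medians (1779 higher, 1312 lower), so some called members are likely in any list. The disagreement between probe sets of 1 gene in these arrays limits these values too. The stress factor Ddit3 rose against WT (2.05, SE 0.28, adjusted p = 0.00158), with the kinase inhibitor Trib3 (1.36) and the chaperone Dnajb9 (1.31), while the chaperone Sdf2l1 fell (-1.64). The unfolded protein response list had 5 of 14 higher and 2 lower (camera adjusted p = 0.742), and its direction by fry turns with the scaling, higher relative to array medians (adjusted p = 0.0138, median 0.60) and lower as deposited (4.05e-04, median -0.11). Of TGF-beta response genes (list adjusted p = 0.931) the activin subunit Inhba rose (3.12, adjusted p = 0.00904), as did the repressors Zeb1 (1.16) and Smad7 (1.06), and the BMP target Id1 fell (-1.48). The p53 targets Phlda3 (-2.80) and Sesn2 (-1.08) fell (list adjusted p = 0.980), as did pro-apoptotic Bak1 (-1.47) and Bad (-1.17) and the antioxidant enzyme Srxn1 (-1.56). The angiogenic factor Vegfa rose (1.60, adjusted p = 0.0335, second probe set -0.29) and Vegfb fell (-1.41). Ribosomal protein genes had 8 of 11 measured members higher and 0 lower (camera adjusted p = 0.0638). By directional fry they are higher relative to array medians (0.00698) and lower as deposited (0.00620). Single genes turn likewise, Rpl4 with 0.59 relative to array medians and -0.12 as deposited, while Rps6 is higher in both (1.51 and 0.80).

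Markers of other cell types gave no list call by camera in any comparison. By directional fry adipocyte markers were lower in DKO than in Ets2KO (adjusted p = 0.0373, as deposited 0.00203). The mixed form of fry, which tests change in either direction, called fibroblast markers (1.09e-04) and macrophage and leukocyte markers (0.0342) there, and the latter also in DKO against Ets1KO (0.00253). Neither form sets a list against other genes, of which 30.1% are called against Ets2KO and 28.5% against Ets1KO. These fry calls therefore cannot show that the marker lists differ from the rest. In Ets2KO against WT, adipocyte markers had a median of 1.30 (3 of 8 measured, adjusted p = 0.187), pericyte markers 0.52 (5 of 8, adjusted p = 0.277), and macrophage and leukocyte markers -0.09 (6 of 14, adjusted p = 0.701). The adipokine Adipoq differs by 4.55 (adjusted p = 0.257) with a wide spread, 10.85 ± 3.24 in Ets2KO and 6.29 ± 3.98 in WT. Smooth muscle markers had a median of 0.44 in DKO against Ets2KO (8 of 12, adjusted p = 0.840), and fibroblast markers 0.46 (12 of 14, adjusted p = 0.950). The matrix protein Dpt, a fibroblast marker, fell in that comparison (-4.16, adjusted p = 0.00233) while Col1a1 and Col1a2 (2.26) rose. Only 9 of 28 endothelial identity genes are among the probe sets, so loss of that identity can be read only in part. Relative to array medians they average -1.98 to -1.73 in the Ets1KO and DKO arrays and -1.49 to -0.50 in the WT and Ets2KO arrays. By directional fry as deposited they are lower in DKO than in WT (adjusted p = 3.58e-04), where the DKO arrays have lower medians.

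Sex differs between arrays. Xist reads 7.26 to 7.50 in the 3 Ets2KO arrays and WT replicate 1, and 11.4 to 13.5 in the others. With sex as a covariate the hypoxia and glycolysis list has a median of -0.78 in Ets2KO against WT. Of the 34 genes called in Ets2KO, 1 is on a sex chromosome. With that covariate, which rests on WT replicate 1 alone, 0 stay called. All 34 keep their direction, and the median absolute log2 is 1.50 against 1.59 without it. Since the genes were called with that array among the WT arrays, their kept direction does not test sex.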
